A study of Homo sapiens with 2 samples.

How the data were processed

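Cells of the 3 lines were stained with barcoded anti-human hashtag antibodies, pooled and run on the 10x Genomics 3' platform, per the labels' protocols. The deposited matrix holds UMI counts, whole numbers for each gene or hashtag and each barcode, made with Cell Ranger 3.0.2 per the file headers and the submitters' processing notes, on genome build GRCh38 per those notes. The annotation version and any barcode filter beyond Cell Ranger are not given in the sources used here. The matrix has 10336 barcodes, 33694 genes and 4 hashtags. The labels tie hashtags 1, 3 and 4 to C1-sgControl, C1-sgEED and C1-sgKMT2D. Hashtag 2 has no line in the labels, so its cells enter no comparison between lines, and their values are only described in the closing sections. No normalised values were used. Results for some genes are not reported here. A 3' count reads the end of a transcript, so isoforms and edits further upstream are not seen.

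Barcodes with under 500 genes or over 20% mitochondrial UMIs were removed, which left 9193 and removed 1143. A barcode was positive for a hashtag above the crossing point of a 2-component Gaussian mixture on the log10 hashtag count. Positive for 1 hashtag, it was given to that line, and the line was never taken from gene expression. Of the barcodes kept, 827 (9.00%) were positive for several hashtags and were removed as doublets, and 26 were positive for none. Doublets of cells with the same hashtag are not seen this way: 282 were expected, or 3.38% of single-hashtag barcodes. They were left in. Scrublet marked 9.86% of the barcodes kept, among them 54.7% of the between-hashtag doublets and 5.81% of the single-hashtag cells of the 3 lines. Removing its calls was tried for the number of clusters only, so all other values include these cells.

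UMIs were summed per line, or per line and range of the M share, and scaled to CPM of all gene UMIs. Cells are not replicates and each line is 1 sample, so no p-value, standard error or count of changed genes was computed. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals at 95%. Log2 ratios use a pseudocount of 1 CPM, which pulls ratios of low genes towards 0. A fold against 0 UMIs is a lower bound against 3 counts over the group. Genes named in the text are the 10 with the highest and the 10 with the lowest log2 ratio among genes of at least 20 CPM in either line, without mitochondrial genes and clone names, plus EED, KMT2D and list members of at least 10 CPM in either line. Members at least 1.5-fold higher or lower were counted. SNRPN, MGMT, NQO1 and the genes named by chromosome were singled out after their values were seen. SAA1 and SAA2, CXCL1, CXCL2 and CXCL3, SERPINB3 and SERPINB4, TRBC2 and the MHC class I genes have close copies whose reads the authors' counting could split, so their levels as single genes are uncertain.

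The 19 gene lists were epithelial genes, mesenchymal genes, EMT transcription factors, epithelial transcription factors, PRC2 members, KMT2D complex members, HOX genes, developmental Polycomb targets, MHC class I, interferon response, TGF-beta and BMP response, luminal genes, squamous differentiation, cytokines and NF-kB, hypoxia and glycolysis, dissociation stress, G1/S, G2/M and surface markers of epithelial and mesenchymal states. Immune, endothelial and neural markers served as lists of other cell types. For 4 list symbols the matrix uses an older name. Each list's median was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression, and medians under percentile 2.5 or over 97.5 were called outside the central range. The lists, the filters, the M share with its bound, the rule for named genes and most of the other settings tried were fixed before the data were examined.

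The M share was planned on cells thinned to 5000 UMIs, or 2000 if fewer than 60% of cells reached 5000. As 47.8% did, 2000 was used. Within-line comparisons of the ranges leave out all genes of the epithelial and mesenchymal lists. Comparisons of the same range between lines keep them, and those list members help to set the ranges. Clusters came from log-normalised counts with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. They were used to say where the ranges lie and were not named. The shared-control values of the overlap come from 100 draws of unchanged lines from control cells. Chromosomes were taken from GENCODE v29 on GRCh38 by gene identifier, and 23 chromosomes were ranked by the median of genes of at least 20 CPM, each in 6 windows of equal gene number. The centring removes the shift of all genes.

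The counting was tested on simulated data drawn from the lines' means and totals. Of the ratio intervals, 95.3% covered the true value over 5110 genes for C1-sgEED over C1-sgControl, 95.5% over 4889 genes for C1-sgKMT2D over C1-sgControl and 95.3% over 4940 genes for C1-sgKMT2D over C1-sgEED. In each of these comparisons 100% of genes changed 1.5-, 2- or 4-fold had the right direction, and 3.5% of 200 unchanged lists lay outside the central range. The simulated sums were Poisson draws, which the intervals assume, so coverage near 95% follows from that model. Its unchanged lists were random genes. The test thus covers counting error, not the uneven spread of UMIs over cells, joint changes of list genes or differences between cultures. The alternatives were other hashtag callers (ratio of the top to the next hashtag of 3 or 10, Seurat HTODemux), no cell filter or a strict one (at least 1000 genes, at most 10% mitochondrial UMIs), equal weight per cell, median-of-ratios scaling, other floors and pseudocounts, totals without mitochondrial and ribosomal genes, other bounds and thinning depths, and other cluster settings. The hashtag ratio of 3 and HTODemux were applied to cell numbers only. Lists without chromosome 16 or 5 genes, thinning to 5000 UMIs, deep cells thinned to 2000 UMIs and checks of ranges and chromosomes were added after the data had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and Seurat 5.3.0 were used.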

Results

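Single-cell transcriptomes were measured in 3 lines derived from C1 cells, an epithelial clone of HMLER, a human mammary epithelial line that has been immortalised and RAS-transformed. The lines carried a control guide (C1-sgControl), a knockout of EED (C1-sgEED) or a knockout of KMT2D (C1-sgKMT2D). EED is a core subunit of the Polycomb repressive complex PRC2, which methylates histone H3 at repressed genes. KMT2D is a methyltransferase that marks histone H3 at enhancers. The design asks whether loss of either gene lets an epithelial line take up mesenchymal expression. The cells were stained with hashtag antibodies, mixed and read as 1 gene expression library with 1 hashtag library, so each line is 1 sample and no difference below has a replicate check. The library titles speak of mixed clones, and the number of clones in each line is not given, so shares of cells within a line do not tell a mix of clones from cells that switched. After filtering, 1720 C1-sgControl, 2338 C1-sgEED and 2348 C1-sgKMT2D cells carried 1 hashtag. They held 9927122, 10256770 and 13957344 UMIs, with medians of 5672.5, 3915 and 5526 UMIs per cell. The filter removed 27.2% of the C1-sgControl cells, 6.78% of the C1-sgEED cells and 5.89% of the C1-sgKMT2D cells. Over the mitochondrial limit were 603 of 2364, 146 of 2508 and 127 of 2495 cells of these lines. All intervals are 95% intervals that cover counting error only. Levels are CPM of a line's gene UMIs, and the place of a list's median among 10000 random lists matched on expression describes these cells only.

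EED (ENSG00000074266; GRCh38 chromosome 11, 86244544 to 86278813, plus strand, protein coding) was read at 13.6 CPM in C1-sgControl, 13.4 CPM (11.2 to 15.8) in C1-sgEED and 15.3 CPM in C1-sgKMT2D. KMT2D (ENSG00000167548; chromosome 12, 49018975 to 49059774, minus strand, protein coding) was read at 4.63 CPM in C1-sgControl, 3.02 CPM in C1-sgEED and 5.02 CPM (3.91 to 6.34) in C1-sgKMT2D. Each transcript was read at a level close to the control in its own knockout, with a ratio to C1-sgControl of 0.982 (0.769 to 1.26) for EED and 1.08 (0.736 to 1.61) for KMT2D. The position of the edits is not given in the sources used here, and a small edit need not change a 3' tag, so these levels check the labels very little. As a list, PRC2 members stood close to the control in both knockouts. The median was 0.14 log2 in C1-sgEED over 11 members and 0.16 in C1-sgKMT2D over 11 members (percentiles 74.2 and 90.9). The catalytic subunit EZH2 was at 14.4 CPM in C1-sgControl, 26.4 in C1-sgEED and 19.8 in C1-sgKMT2D. For the partners of KMT2D, 5 members were measured, with medians of 0.11 and 0.03 (mean -0.02 in C1-sgKMT2D), and none of them differed by 1.5-fold in either knockout.

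C1-sgEED cells together had higher levels of most mesenchymal list genes than C1-sgControl cells, and lower levels of most epithelial and cytokine list genes. MGP, an extracellular matrix protein that inhibits calcification, was at 261 CPM against 1.51, or 173-fold higher (104 to 309). An MGP UMI was found in 16.4% of C1-sgEED cells of at least 2000 UMIs. PTX3, a secreted pattern-recognition protein, was 75.7-fold higher (56.8 to 103), and the fibrillar collagen COL3A1 was at 72.8 CPM against 0.705, or 103-fold higher (49.9 to 258). The other genes among the 10 with the highest ratios were CADM3, the growth factor binding proteins IGFBP3 and IGFBP2, the syndecan SDC2, the elastic fibre proteins FBLN5 and FBN1, and TRBC2. They ranged from 24.7-fold for IGFBP2 (20.1 to 30.8) to 236-fold for SDC2 (41.99 to 9365), which had 1 UMI in C1-sgControl. The 10 with the lowest ratios were led by CSF3, which encodes granulocyte colony-stimulating factor, at 3.22 CPM against 39.2, or 12.2-fold lower (8.53 to 17.9). The acute-phase genes SAA2 and SAA1 followed at 10.2-fold (7.85 to 13.5) and 9.61-fold lower (8.97 to 10.3). The others were CASP14, TREM2, LTB, BIRC3, SERPINB2, IL1B and CXCL1, down to 4.96-fold lower for CXCL1 (4.30 to 5.75).

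Of the 30 measured mesenchymal list members, 20 were at least 1.5-fold higher in C1-sgEED and 0 were lower (median 1.35 log2, percentile 100). COL6A3 stood at 32.0 CPM against 1.61 and periostin (POSTN) at 17.3 against 0.101. Fibronectin (FN1) was level over the whole line, at 2580 against 2514 CPM, though not within the ranges of the M share (below). Of the 41 epithelial members, 29 were lower and 1 was higher (median -0.89, percentile 0). The basal keratin KRT14 was at 366 CPM against 1531 and E-cadherin (CDH1) at 22.5 against 65.8, whereas EPCAM was higher at 91.5 against 57.5. Epithelial transcription factors were lower as a list, with 8 of 10 members lower and GATA3 higher (median -0.80, percentile 0). The p53 family member TP63 was at 8.77 CPM against 23.4. The list of EMT transcription factors had a median of 0.11 (percentile 45.9), with 2 of 11 members lower and 3 higher: ZEB1 at 17.5 CPM against 0.604, ZEB2 at 11.3 against 0.907 and FOXC2 at 29.6 against 5.94. That median was above the central range with members of at least 2 CPM (0.47) and below it with members of at least 50 CPM (-0.76). The cytokine and NF-kB list was the lowest, with 14 of 17 members lower and 0 higher (median -1.50, percentile 0). The squamous list (median -0.86, 5 of 10 lower, percentile 0) and the hypoxia list (median -0.40, 7 of 19 lower, percentile 0) were also below all random lists.

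Cell cycle genes were higher in C1-sgEED, with 20 of 38 G1/S members and 38 of 51 G2/M members at least 1.5-fold higher and none lower (medians 0.61 and 0.84, both percentile 100). CDK1, the kinase that drives entry into mitosis, was at 118 CPM against 45.9. Interferon response genes had a median of 0.40 (percentile 98.4), with 3 of 10 higher, among them ISG15 at 73.9 CPM against 27.6. Repressed developmental genes known as Polycomb targets were mostly not measurable: 12 of 98 reached 10 CPM, with 3 higher, 1 lower and a median of 0.02 (percentile 35.6). With members of at least 2 CPM their median was 0.38, above the central range (percentile 98.1). Of 39 HOX genes, 6 were measured, and HOXB9 (13.8 CPM against 2.92) and HOXC13 (11.2 against 6.35) were at least 1.5-fold higher (median 0.36, percentile 88.0). Lists within the central range of random lists were MHC class I (median 0.06), TGF-beta and BMP response (0.07), luminal genes (-0.05), dissociation stress (0.14) and surface markers of epithelial and mesenchymal states (-0.13). The surface markers were near its edge (percentile 2.68). Several alternatives put them below it, among them the strict cell filter (-0.19) and members of at least 50 CPM (-0.23). The mean had the opposite sign for MHC class I (-0.04). In the TGF-beta list the matrix gene CTGF stood at 177 CPM against 21.0 and INHBA at 125 against 407. The median log2 ratio of all measured genes was 0.11, a shift that the scaling to total UMIs leaves in this comparison.

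C1-sgKMT2D cells together also had lower levels of most epithelial list genes than C1-sgControl cells, and higher levels of some mesenchymal list genes. TNFAIP6, a hyaluronan-binding protein induced by inflammation, was at 70.0 CPM against 1.01, or 69.5-fold higher (37.6 to 145). COL3A1 was 83.6-fold (40.4 to 209) and the proteoglycan decorin (DCN) 74.7-fold higher (36.1 to 186), at 52.7 CPM against 0.705. CADM3, the tryptophan catabolism enzyme KYNU, the interleukin-33 receptor IL1RL1, FABP4, SERPINB4, COL6A2 and PID1 completed the highest 10, down to 13.7-fold for PID1 (10.0 to 19.2). Among the lowest 10, lymphotoxin beta (LTB) was at 11.5 CPM against 205, or 17.8-fold lower (15.1 to 21.0), and the cornified envelope gene SPRR1B at 7.81 against 136, or 17.4-fold lower (14.3 to 21.4). LCN2, CST6, SERPINB2, CASP14, FST, the gelatinase MMP9, TREM2 and IL32 made up the rest, down to 10.7-fold for IL32 (8.76 to 13.2).

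Of the 41 epithelial members, 33 were lower in C1-sgKMT2D and 0 higher (median -0.88, percentile 0). CLDN4, a tight junction claudin, was at 4.66 CPM against 50.97 and CDH1 at 15.3 against 65.8. CDH1, CDH3 and MARVELD3 of this list lie on chromosome 16, where nearly all genes were lower in this line (below). Without chromosome 16 genes the median was -0.86. The mesenchymal list went both ways, with 9 of 24 members higher and 7 lower. Its median was -0.21 (percentile 2.90) and its mean 0.69, so the sign depends on the summary. COL6A2 (98.9 CPM against 6.95) was higher, as was vimentin (VIM) at 3541 against 1150, while SPARC (48.9 against 115), TAGLN (6.45 against 22.5) and S100A4 (18.6 against 44.2) were lower. Epithelial transcription factors were lower for 7 of 10 members (median -0.80, percentile 0.1), with EHF at 0.645 CPM against 11.9. EMT transcription factors had 3 of 9 members higher and 2 lower (median 0.10, percentile 80.2), the higher being ZEB2 (14.2 CPM against 0.907), FOXC2 and TWIST1. With members of at least 2 CPM the median was 0.33, above the central range.

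Cytokine genes split in C1-sgKMT2D. The list had 5 of 18 members higher and 7 lower (median -0.33, percentile 1.22). It was within the central range without IL32, which lies on chromosome 16 (-0.23, percentile 5.43), as a mean over cells (-0.21) and without mitochondrial and ribosomal genes in the total (-0.17). IL6 was at 15.8 CPM against 2.22 and CXCL8 at 103 against 52.8, while IL1B was at 30.4 against 164. Luminal genes (median -0.60, 4 of 7 lower), squamous genes (-0.48, 3 of 8), MHC class I genes (-0.39, 4 of 12), hypoxia genes (-0.54, 9 of 19) and surface markers (-0.41, 5 of 12) lay below the central range of their random lists. With members of at least 50 CPM the luminal (-0.32), squamous (-0.29) and MHC class I (-0.23) medians were within it. CD24 stood at 47.2 CPM against 227 and the peptide transporter TAP1 at 17.6 against 38.0. Cell cycle lists were higher, with 10 of 36 G1/S and 31 of 51 G2/M members at least 1.5-fold higher and none lower (medians 0.34 and 0.66, percentile 100 each). Interferon (0.08, with a mean of -0.13), TGF-beta and BMP (-0.10), HOX (-0.07), Polycomb target (-0.07) and dissociation stress (0.10) medians lay within the central range.

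The direct comparison of the knockouts has no shared control. TAGLN, an actin-binding protein of smooth muscle, was at 6.45 CPM in C1-sgKMT2D and 225 in C1-sgEED, or 34.9-fold lower (28.3 to 43.6). IGFBP3 was 50.3-fold (31.1 to 86.8) and MGP 18.3-fold lower (15.8 to 21.2), and IGFBP2, TRBC2, CRCT1, LOXL1, CST6 and MAP1B were among the lowest 10 as well. KYNU was 39.5-fold (23.8 to 70.9) and TNFAIP6 31.2-fold higher (20.7 to 49.5) in C1-sgKMT2D. The mitochondrial superoxide dismutase SOD2 was at 617 CPM against 89.2, and the neutrophil chemokine CXCL1 at 168 against 22.4, or 7.50-fold higher (6.55 to 8.62). The mesenchymal list was lower in C1-sgKMT2D for 18 of 31 members and higher for 2 (median -0.97, percentile 0), the 2 being DCN and SERPINF1. The epithelial list did not separate them (median -0.01, 3 higher and 5 lower of 39, percentile 89.0). The cytokine list was higher in C1-sgKMT2D for 10 of 16 members and lower for 2 (median 0.94, percentile 100). Luminal (-0.89), squamous (-0.57), interferon (-0.56), MHC class I (-0.52) and TGF-beta and BMP genes (-0.50) had medians below the central range. As a mean over cells the squamous (-0.39) and interferon (-0.18) medians were within it, as was the squamous median with members of at least 50 CPM (-0.05). The median of all genes was -0.11 here. Across the 3 comparisons 57 list medians were ranked, and 26 lay outside the central 95% of their random lists.

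**Figure D1:**
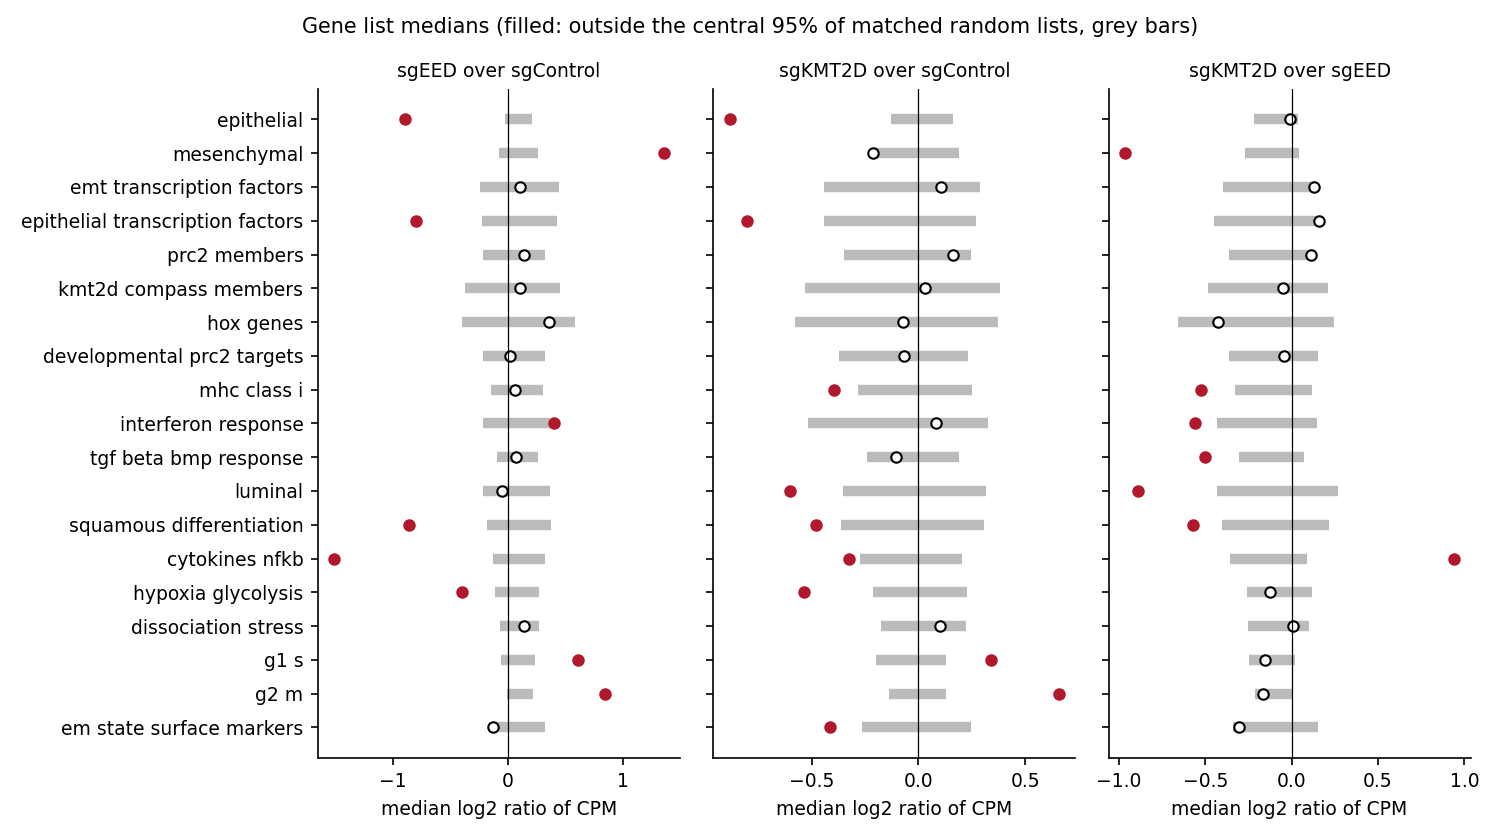
Median log2 ratio of CPM (x axis) of each of 19 gene lists (y axis) in the 3 comparisons between lines; grey bars span the central 95% of 10000 random lists matched on expression, and filled points lie outside it. The mesenchymal median is 1.35 in sgEED and -0.21 in sgKMT2D, while the epithelial medians are -0.89 and -0.88.

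The differences of the knockouts from the control were compared across 5631 genes of at least 20 CPM. Their log2 ratios over the same control cells had a Pearson r of 0.621 and a Spearman rho of 0.572 across genes, which are not independent replicates. Unchanged lines drawn from the control cells gave a median r of 0.577 and a maximum of 0.658 in 100 draws, from the shared control alone. The observed r lies within their range, so r over shared control cells cannot judge the overlap. The covariance, which also reflects the size of the changes, was 0.214, against a median of 0.00523 in those draws. With the control cells split at random between the comparisons r was 0.594 and the covariance 0.209. Sharing of control cells thus does not account for the covariance or for the r of the split, though both comparisons still rest on 1 control sample. COL3A1, DCN, MGP and PTX3 were higher and CSF3, LTB and SPRR1B lower in both knockouts. TAGLN and IGFBP3 were higher in C1-sgEED and not in C1-sgKMT2D, and KYNU was higher in C1-sgKMT2D only among the 2 knockouts.

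**Figure D2:**
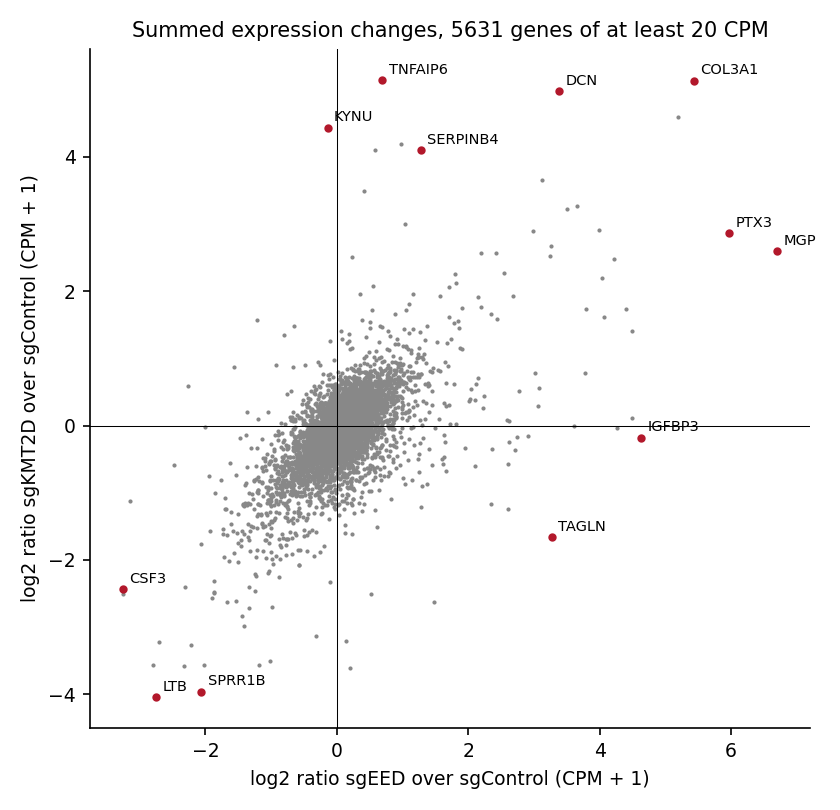
Log2 ratio of CPM plus 1 to sgControl in sgEED (x axis) and in sgKMT2D (y axis), 1 point for each of 5631 genes, with named genes in red. Pearson r is 0.621 across genes, against a median of 0.577 and a maximum of 0.658 for unchanged lines that share the control cells. With the control cells split between the comparisons r is 0.594. The covariance is 0.214, against a median of 0.00523 for those lines.

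Each knockout held cells with mostly epithelial and cells with mostly mesenchymal list UMIs, and C1-sgKMT2D also held cells in between. For each cell thinned to 2000 UMIs, the M share was taken as the UMIs of the mesenchymal list over those of the mesenchymal and epithelial lists. Above the 99th percentile of C1-sgControl (0.532), called the mesenchymal range here, lay 17 of 1636 C1-sgControl cells, 1020 of 2171 C1-sgEED cells (47.0%, 44.9 to 49.1) and 986 of 2234 C1-sgKMT2D cells (44.1%, 42.1 to 46.2). Without thinning the shares were 1.05%, 48.7% and 45.3%. Thinning left out 84, 167 and 114 shallower cells. Within 0.05 of the bound lay 50, 65 and 69 cells, and the range is an interval of a score, not a cell type. Between the bound and 0.8 lay 54 C1-sgEED cells (2.49%, 1.87 to 3.23) and 280 C1-sgKMT2D cells (12.5%, 11.2 to 13.98). The share depends on depth, because mesenchymal-range cells were shallower (medians of 3567.5 and 4439.5 UMIs, against 4532 and 6949.5 in the epithelial range). Among cells of at least 5000 UMIs, thinned to that depth, it was 31.8% in C1-sgEED and 30.4% in C1-sgKMT2D, and at 10000 UMIs 23.5% and 17.2%. The same deep cells gave nearly these shares when thinned to 2000 UMIs. Of 7 clusters, cluster 3 held 95.5% of the mesenchymal-range C1-sgEED cells, and clusters 4 and 6 held 79.2% and 15.8% of those of C1-sgKMT2D. In the epithelial range, most cells lay in cluster 2 for C1-sgControl (77.0%), 0 for C1-sgEED (63.7%) and 5 for C1-sgKMT2D (64.98%).

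**Figure D3:**
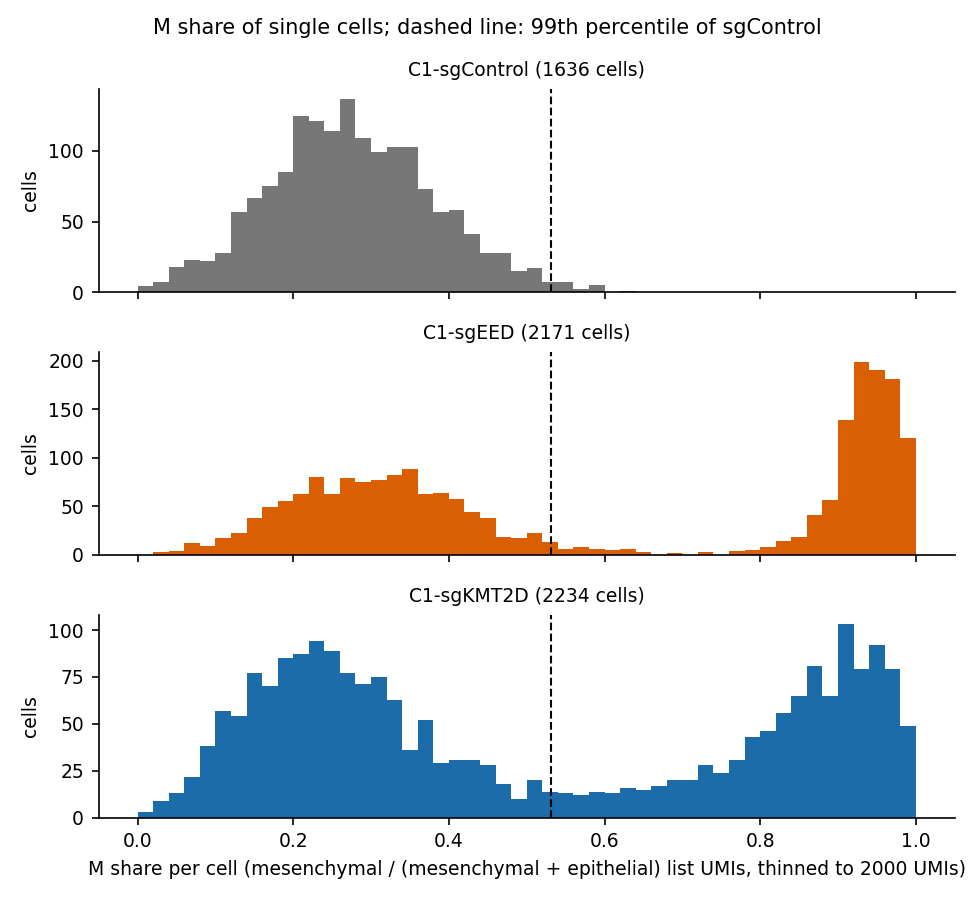
Number of cells (y axis) by M share (x axis, UMIs of the mesenchymal list over those of both lists, cells thinned to 2000 UMIs) in the 3 lines; the dashed line is the 99th percentile of sgControl, 0.532. Above it lie 17 of 1636 sgControl, 1020 of 2171 sgEED and 986 of 2234 sgKMT2D cells, and 280 sgKMT2D cells lie between it and 0.8.

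The comparisons of genes between ranges across lines were chosen after the M share had been seen. Mesenchymal-range cells of both knockouts carried ZEB1, a repressor of epithelial genes (ENSG00000148516; chromosome 10, 31318495 to 31529814). It was read at 42.1 CPM in C1-sgEED and 22.3 in C1-sgKMT2D, against 0.618 in epithelial-range C1-sgControl cells. In thinned cells a ZEB1 UMI was found in 8.04% (6.44 to 9.88) of mesenchymal-range C1-sgEED cells and 4.26% (3.09 to 5.71) of those of C1-sgKMT2D. Epithelial-range C1-sgControl cells, with a median of 5806 UMIs before thinning, gave 0.124% as the background. Without thinning these shares were 15%, 10.5% and 0.371%. No thinned cell held both CDH1 and ZEB1 UMIs, or both CDH1 and CDH2, in any line. At 2000 UMIs CDH1 was found in only 11.4% of C1-sgControl cells, so this sets no limit on cells with both. Without thinning 4 C1-sgControl, 0 C1-sgEED and 2 C1-sgKMT2D cells held CDH1 with ZEB1, and 2, 0 and 1 held CDH1 with CDH2. EPCAM and VIM UMIs were found together in 8.44%, 11.9% and 10.1% of thinned cells of the 3 lines, and in 23.7%, 25.3% and 27.3% of the same cells without thinning. VIM itself was found in 80.7% of thinned C1-sgControl cells, so this pair marks no mixed state.

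**Figure D4:**
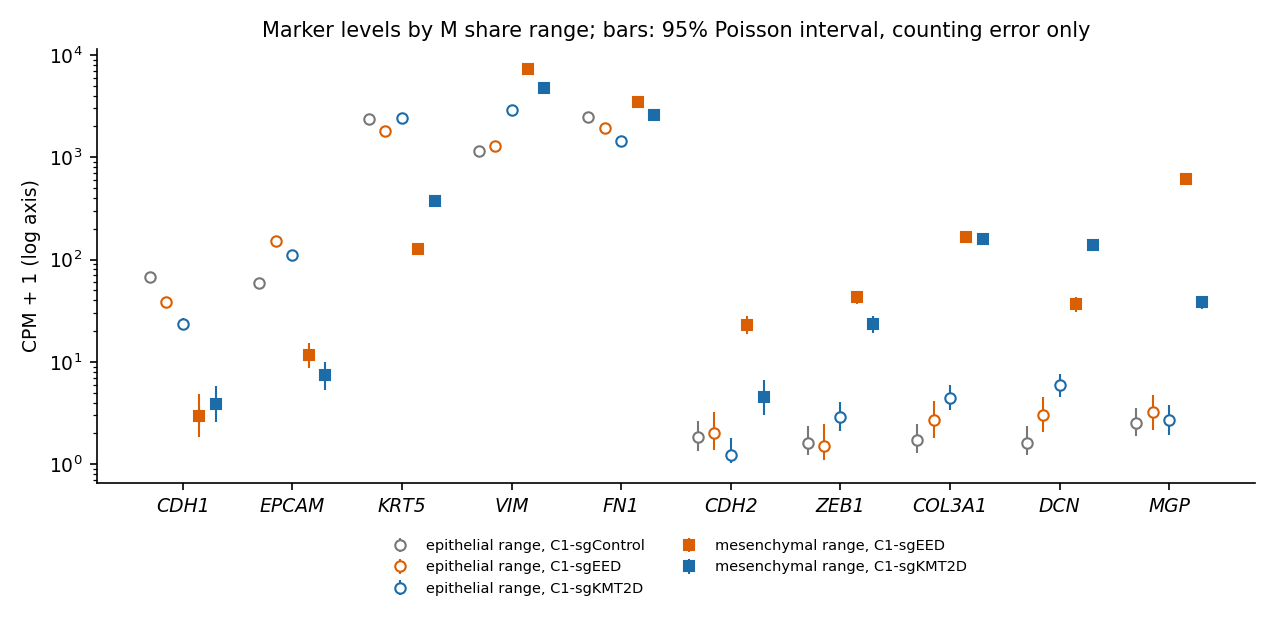
CPM plus 1 (y axis, log scale) of 10 genes (x axis) in epithelial-range cells of the 3 lines and mesenchymal-range cells of the knockouts, with 95% Poisson intervals that cover counting error only; the 17 control cells above the bound are not drawn. CDH1, EPCAM, KRT5, VIM, FN1, CDH2, COL3A1 and DCN are part of the M share, and ZEB1 and MGP are not.

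Within C1-sgEED, mesenchymal-range cells were compared with epithelial-range cells for genes outside the M share, and the same was done within C1-sgKMT2D. MGP was at 616 CPM against 2.21 in C1-sgEED, or 278-fold higher (162 to 523), and PTX3 at 837 against 7.67. An MGP UMI was found in 28.0% of thinned mesenchymal-range C1-sgEED cells, and in 33.8% of them without thinning. Most cells of that range thus held no MGP UMI. The fatty acid binding protein FABP4 led in C1-sgKMT2D at 102 CPM against 0.112, with 1 UMI in the epithelial range, followed by TNFAIP6 at 191 against 4.59. In both lines CADM3 was higher and MPZL2 and FXYD3 lower in the mesenchymal range. EMT transcription factors as a list lay within the central range in C1-sgEED (median 0.14, 6 of 12 higher and 3 lower, percentile 82.1) and in C1-sgKMT2D (0.06, 4 of 10 higher and 2 lower, percentile 73.99). ZEB1, ZEB2 and FOXC2 were higher and SOX9 lower in both. Epithelial transcription factors were lower for 10 of 11 members in C1-sgEED (median -2.72) and 7 of 8 in C1-sgKMT2D (-1.76), ESRP1 in both. The luminal (medians -2.77 and -1.27) and squamous lists (-3.25 and -0.58) were lower too. The interferon list was higher, with 7 of 13 members higher and 2 lower in C1-sgEED (0.64) and 8 of 11 higher and 1 lower in C1-sgKMT2D (1.22), and the interferon-induced IFI44L at 10.6 and 15.5 CPM against 0.341 and 0.672. MHC class I genes were higher in C1-sgKMT2D (0.47, 4 of 12 higher and 0 lower, percentile 100) and within the central range in C1-sgEED (-0.04, percentile 27.3). Cytokine genes went opposite ways. In C1-sgEED 10 of 13 members were lower and 0 higher (median -1.13), while in C1-sgKMT2D 15 of 17 were higher and 1, IL1A, lower (median 1.56), with CXCL8 at 238 CPM against 27.4 and CXCL1 at 400.1 against 40.7. The dissociation stress list, which was within the central range between whole lines, was lower for 12 of 21 members and higher for 1 in C1-sgEED (median -0.66, percentile 0), with ATF3 at 88.5 CPM against 209.7 and JUN at 356 against 685. In C1-sgKMT2D 4 were higher and 4 lower (-0.22, percentile 0.73; -0.16 and within the central range under the strict cell filter). HOX genes had a median of 0.56 in C1-sgEED (percentile 98.9) and 0.18 in C1-sgKMT2D (percentile 83.0).

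Mesenchymal-range cells also differed between the knockouts. TAGLN was at 8.05 CPM in C1-sgKMT2D and 511 in C1-sgEED, or 63.5-fold lower (46.3 to 89.6). The smooth muscle actin ACTG2, the receptor EPHB6, the adhesion molecule NCAM1 and the phosphatase ALPL had 0 UMIs in C1-sgKMT2D and were at least 69.5-, 61.7-, 45.3- and 35.9-fold lower against a floor of 3 counts over the group. The lower limits of their 95% intervals, which the other folds carry, were smaller at 55.9, 49.6, 36.3 and 28.6. The growth factor receptor PDGFRB was at 1.24 CPM against 21.0, and its relative PDGFRA at 18.6 against 0.967. The mesenchymal list was lower in C1-sgKMT2D for 20 of 33 members and higher for 5 (median -0.85, percentile 0). The cytokine list was higher for 15 of 16 and lower for 0 (median 2.68, percentile 100). The dissociation stress list was higher for 10 of 20 and lower for 3 (median 0.52, percentile 100). The S100 genes S100A9 (328 CPM against 19.8) and S100A8 (110 against 9.19) were higher in C1-sgKMT2D, and all 7 measured HOX genes had lower values, 5 of them by at least 1.5-fold (median -0.77, percentile 0.710).

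Epithelial-range cells of the knockouts were not the same as control cells. In C1-sgEED the dissociation stress list was higher for 7 of 21 members and lower for 1 (median 0.24, percentile 99.6). The squamous list had 5 of 13 members higher, such as CNFN, and 5 lower, such as SPRR1B (median 0.34, percentile 97.9), unlike its lower median in the whole line. The cytokine list was lower for 12 of 17 members and higher for 1 (median -1.05, percentile 0), and the epithelial list was lower for 10 of 41 and higher for 4 (median -0.23, percentile 0). EPCAM (ENSG00000119888; chromosome 2, 47345158 to 47387601) was at 151 CPM against 57.4, IGFBP2 at 134 against 9.07 and the proteoglycan VCAN at 23.2 against 2.47. The mesenchymal list did not stand apart there (median 0.07, 3 higher and 1 lower of 22, percentile 49). Its gene FN1 was at 1933 CPM in these cells and 3440 in mesenchymal-range C1-sgEED cells, against 2489 in control cells. The epithelial and mesenchymal lists set the range, which leaves out cells of high M share. Their medians among epithelial-range cells of either knockout are therefore partly fixed in advance. In C1-sgKMT2D the cytokine list was lower for 13 of 17 and higher for 0 (median -0.91, percentile 0), and MHC class I genes were lower for 6 of 12 (median -0.58, percentile 0), with HLA-B at 74.3 CPM against 162. The epithelial list was lower for 17 of 41 members and higher for 2 (median -0.42, percentile 0). The mesenchymal list was lower too, for 9 of 20 members and higher for 3 (median -0.45, percentile 0), with FN1 at 1430.2 CPM against 2489. Against that list, epithelial-range C1-sgKMT2D cells held more VIM (ENSG00000026025; chromosome 10, 17228259 to 17237593) than control cells, at 2897 CPM against 1147, or 2.53-fold higher (2.47 to 2.58). Their CDH1 (ENSG00000039068; chromosome 16, 68737225 to 68835548) was at 22.3 CPM against 65.8, or 2.96-fold lower (2.52 to 3.48). In C1-sgEED these genes stood at 1278 and 37.1 CPM. Hypoxia genes were lower in both (medians -0.34 and -0.51), and G2/M genes higher (0.53 and 0.65). These lists and the cytokine list moved the same way in both knockouts against the same control cells. A difference in C1-sgControl alone could give such shared shifts.

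The G2/M list took 0.298% (0.295 to 0.302) of UMIs in C1-sgControl, 0.528% (0.523 to 0.532) in C1-sgEED and 0.447% (0.444 to 0.451) in C1-sgKMT2D. The G1/S list took 0.128%, 0.201% and 0.170%. In thinned cells, 22.3% of C1-sgEED and 14.9% of C1-sgKMT2D cells had a G2/M share above the 90th percentile of C1-sgControl, which 9.29% of the control cells exceeded. For G1/S these shares were 18.7%, 10.3% and 7.89%. Without thinning they were 22.98%, 15% and 10.0% for G2/M, and 24.5%, 13.7% and 10.0% for G1/S. Among thinned cells, 30.7% of mesenchymal-range C1-sgEED and 13.4% of mesenchymal-range C1-sgKMT2D cells were above the control G1/S percentile. In the epithelial range it was 8.08% in C1-sgEED, 7.85% in C1-sgKMT2D and 7.78% in C1-sgControl. As a share of UMIs, G1/S was higher in the epithelial range too. It was 0.159% (0.155 to 0.162) in C1-sgEED and 0.158% in C1-sgKMT2D, against 0.128% (0.126 to 0.130) in C1-sgControl. The G1/S list medians of these cells over control were 0.29 and 0.26 (percentiles 99.9 and 99.98). For G2/M the mesenchymal range held 28.0% and the epithelial range 17.3% of thinned cells above the control percentile in C1-sgEED, against 14.7% and 14.98% in C1-sgKMT2D. The G2/M share of UMIs in C1-sgKMT2D was higher in its mesenchymal range, at 0.483% (0.477 to 0.489) against 0.432% (0.427 to 0.436) in its epithelial range. Intervals of such UMI shares take UMIs as independent, which UMIs of the same cell are not. As a mean over cells the G2/M share of all C1-sgKMT2D cells was 0.379%, against 0.447% of summed UMIs. The weighting of cells thus matters, and the difference between these ranges is not firm. Between the ranges of 1 line, the G1/S and G2/M medians were 0.63 and 0.62 in C1-sgEED and 0.27 and 0.12 in C1-sgKMT2D, above the central range. The G2/M median of C1-sgKMT2D was within that range for M shares above 0.8 (0.02). No phase was assigned, and free RNA from other cells stays open for such shares. Markers of other cell types were nearly absent: of the immune, endothelial and neural lists, CD68 (14.7 to 19.8 CPM) and MBP (23.5 to 36.7 CPM) alone reached 10 CPM in a line.

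Genes of chromosome 16 were lower as a group in C1-sgKMT2D, a comparison made after the data had been seen. Their median log2 ratio to C1-sgControl, centred on all genes, was -0.69 over 209 genes, with 95.7% of them below 0. The lowest of the other 22 chromosomes was chromosome 14 at -0.10. The medians of 6 windows along chromosome 16 ran from -0.80 to -0.45, and the value was -0.69 in the epithelial and -0.73 in the mesenchymal range. Besides CDH1 and CDH3, it carries other list genes, among them IL32, ALDOA, ESRP2, CDH11 and MARVELD3, which were lower. FOXC2 and IRX3 lie there too and were higher, at 25.1 CPM against 5.94 and 17.1 against 10.8. Genes of chromosome 5 were higher in mesenchymal-range than in epithelial-range C1-sgEED cells (median 0.42 over 297 genes, 82.8% above 0), and much less so in C1-sgKMT2D (0.06, percentile 99.1). Chromosome 10 genes were higher in both knockouts (0.17 in C1-sgEED, 0.29 in C1-sgKMT2D). They were highest in the first windows of the chromosome, which hold VIM and ZEB1, at 0.42 and 0.38 in C1-sgEED and 0.55 and 0.42 in C1-sgKMT2D; the other windows reached at most 0.14 and 0.27. Both ratios use the same control cells, and C1-sgKMT2D over C1-sgEED gave 0.04 (percentile 92.6), so a lower level in C1-sgControl alone would give the same values.

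**Figure D5:**
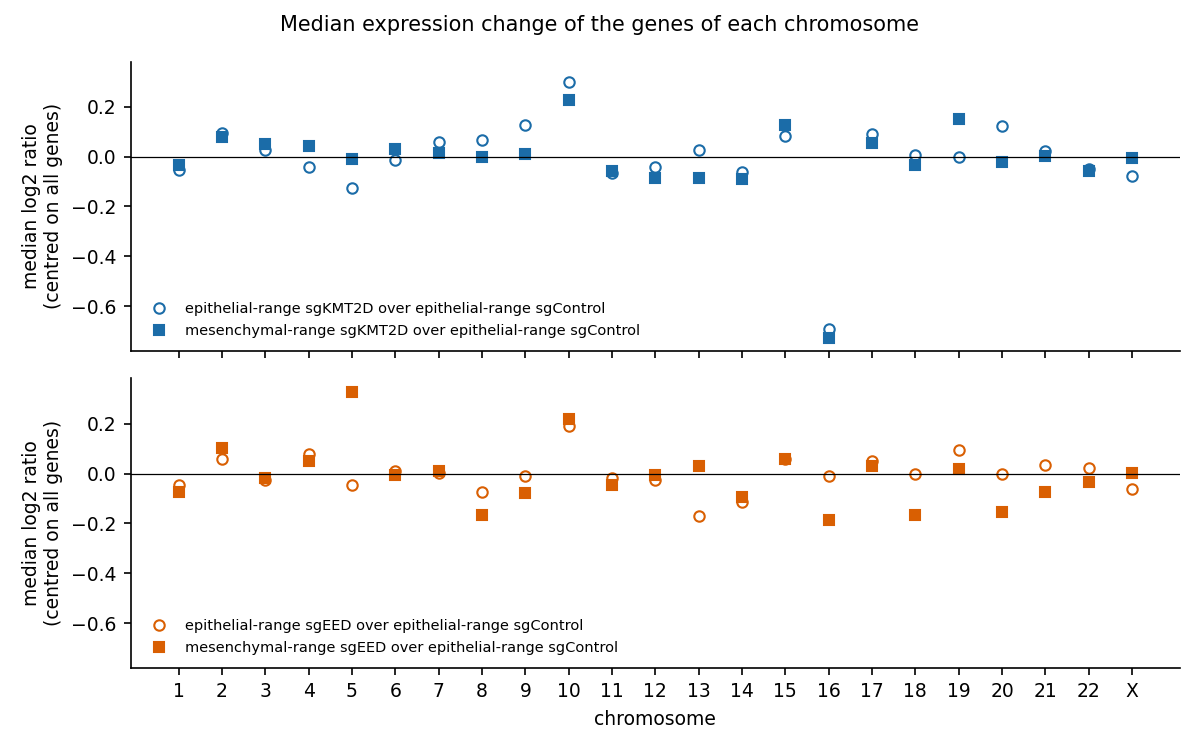
Median log2 ratio of the genes of each chromosome (y axis, centred on all genes; x axis, chromosome) over epithelial-range sgControl cells, for sgKMT2D (upper panel) and sgEED (lower panel); circles are epithelial-range and squares mesenchymal-range cells. Chromosome 16 is at -0.69 and -0.73 in sgKMT2D, and chromosome 5 at 0.33 in mesenchymal-range and -0.04 in epithelial-range sgEED.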

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

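The comparisons of ranges across lines and the tests on chromosomes 16 and 5 were chosen only after the result was seen, except the test without strongly changed chromosome 5 genes; the tests on cells of middle M share were fixed before their values were seen.

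Cells of hashtag 2, which has no line in the labels, had a median M share of 0.545. Of the 1856 cells of sufficient depth, 50.8% lay above the bound of 0.532. A median close to the bound does not tell cells near it from separate groups on either side, and their spread is not given here. The interferon list, in epithelial-range cells against epithelial-range C1-sgControl cells, had a median of 0.38 in C1-sgEED and -0.52 in C1-sgKMT2D. The cytokine list, in mesenchymal-range against epithelial-range cells of the same line, had a median of -1.13 in C1-sgEED and 1.56 in C1-sgKMT2D. These differences between the knockouts were not tested, as each line is 1 sample.

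Chromosome 16 genes were lower in C1-sgKMT2D. A scaling difference is argued against by the median of -0.69 after centring on all genes, far below the next chromosome at -0.10. A minority of cells is argued against by the share of C1-sgKMT2D cells whose chromosome 16 UMIs, without genes over 500 CPM, lie below the control median, 96.2% (95.3 to 96.9); with all genes it was 78.8%, and the abundant metallothionein MT2A was left out after that value was seen. With 95.7% of genes below 0 and every window low in both ranges, loss of a copy of chromosome 16 in this line is a hypothesis that may account for part of the lower CDH1, CDH3 and IL32. A chromatin effect of the KMT2D knockout across the chromosome stays open, since no DNA was analysed here.

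Chromosome 5 genes were higher in mesenchymal-range than in epithelial-range C1-sgEED cells. A few strong genes are argued against by the median of 0.34 over the 242 genes that differed less than 2-fold. A change that goes with the mesenchymal range in either knockout is argued against as the main cause by the same median in C1-sgKMT2D, 0.063, a far smaller shift though above its random lists. With 82.8% of genes above 0 and window medians from 0.27 to 0.51, an extra copy of chromosome 5 in mesenchymal-range C1-sgEED cells is a hypothesis, and the 2 ranges may then hold separate clones. An expression change of these cells without a change in copies stays open.

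More C1-sgKMT2D than C1-sgEED cells lay between the bound and an M share of 0.8. Doublets of an epithelial-range and a mesenchymal-range cell are argued against as the whole cause, with 280 cells against 38.0 expected, or 7.37 times; in C1-sgEED the 54 cells were 1.25 times the 43.0 expected. Counting noise is argued against as the main cause: among deep C1-sgKMT2D cells the number at 5000 UMIs was 0.940 times that at 2000 UMIs with the bound of each depth (0.515 and 0.532) and 0.868 times with 0.532 at both, and of the 151 cells 105 (69.5%) were there at both depths, 29 moved above 0.8 and 17 to the bound or below; the depths share UMIs, and these counts and the single bound were added after the first ratio was seen. Free RNA cannot be told apart: these cells held a median of 9 epithelial UMIs, 3 times that of C1-sgEED cells above 0.8 (2.67 to 3.33), and the interval spans the limit of 3 set in advance, where the need for the interval to clear it was added after the value was seen. These cells were selected for M shares up to 0.8, so a ratio above 1 follows in part from the selection. It therefore cannot decide on free RNA. An intermediate expression state of C1-sgKMT2D cells may be part of this group and remains a hypothesis.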

How the results depend on the processing

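The 5000-UMI depth, the deep cells at 2000 UMIs, the lists without chromosome 16 or 5 genes and the checks of ranges and chromosomes were chosen after seeing the data. No list median outside its random lists and no ratio with an interval excluding 1 changed direction. Of 206 alternative list medians in each comparison, 196 for C1-sgEED, 195 for C1-sgKMT2D over C1-sgControl and 192 between the knockouts kept their side of the central range. The mesenchymal median of C1-sgKMT2D over C1-sgControl left that range at -0.29 without a cell filter, -0.22 without mitochondrial and ribosomal genes in the total and -0.20 with a pseudocount of 5 CPM. The epithelial median of C1-sgKMT2D over C1-sgEED went from -0.01 to 0.13 under the strict cell filter, above the central range. The mesenchymal-range share of C1-sgEED and C1-sgKMT2D was 50.0% and 46.7% with the 95th percentile, 31.8% and 30.4% at 5000 UMIs, 23.5% and 17.2% at 10000 UMIs (51 and 232 cells) and 52.4% and 41.5% under the strict filter; for C1-sgKMT2D it was 47.5% without the most abundant marker of each list. Cells of at least 5000 UMIs gave 31.5% and 30.2%, and of at least 10000 UMIs 23.5% and 17.2%, when thinned to 2000 UMIs with the same bound, so the lower shares come from taking deep cells. Cells with EPCAM and VIM were 45.2% of C1-sgControl, 72.5% of C1-sgEED and 47.8% of C1-sgKMT2D cells at 10000 UMIs, and 22.7%, 23.8% and 26.4% of all cells without thinning. The G1/S share of UMIs was 0.119% in C1-sgControl and 0.165% in C1-sgKMT2D as a mean over cells, and 0.133% in C1-sgControl and 0.212% in C1-sgEED under the strict filter. The G2/M share in the 3 lines was 0.266%, 0.493% and 0.379% as a mean over cells and 0.309%, 0.565% and 0.493% under the strict filter. Resolution 1.0 gave 12 clusters. Other causes were not tested. Of 300 alternative values of named genes, 83 left the interval of the gene's ratio. Of 144 list medians between ranges, 7 entered and 5 left the central range; those that entered include, in C1-sgKMT2D, dissociation stress under the strict filter (-0.16) and G2/M with M shares above 0.8 (0.02). Between lines, 6 and 3 medians entered it: for C1-sgKMT2D over C1-sgControl MHC class I (-0.23), luminal (-0.32) and squamous genes (-0.29) with members of at least 50 CPM, and cytokines as a mean over cells (-0.21), without mitochondrial and ribosomal genes (-0.17) or without chromosome 16 (-0.23); between the knockouts interferon (-0.18) and squamous genes (-0.39) as a mean over cells, and squamous genes of at least 50 CPM (-0.05). The 15 alternative cell numbers stayed within 1.5-fold and the 20 target gene ratios within their intervals. Depth limits lowly expressed genes: most Polycomb targets and both edited genes have few UMIs. No paired analysis was possible because all lines come from 1 library without replicates.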

Other observations

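All values here were singled out after the data had been seen. Epithelial-range C1-sgEED cells almost lacked SNRPN, a splicing protein gene on chromosome 15 that is expressed from the paternal copy. It was read at 1.53 CPM (0.701 to 2.91), against 50.5 CPM in epithelial-range C1-sgControl cells, or 32.9-fold lower (17.2 to 72.4). Mesenchymal-range cells of the same line held 42.3 CPM, and both ranges of C1-sgKMT2D 62.3 and 49.9 CPM. The DNA repair gene MGMT behaved alike in that range, at 2.56 CPM against 39.7 in control cells, or 15.5-fold lower (9.29 to 28.0), with 17.9 CPM in mesenchymal-range C1-sgEED cells. The imprinted long non-coding RNA MEG3 was at 121 CPM in epithelial-range and 62.6 in mesenchymal-range C1-sgEED cells, against 40.6 in control cells. PKIB, an inhibitor of protein kinase A, was at 93.3 and 99.1 CPM in the 2 ranges of C1-sgEED and at 18.9 and 3.71 in those of C1-sgKMT2D, against 17.9 in control cells. The antioxidant enzyme gene NQO1, on chromosome 16, was at 299.7 CPM in mesenchymal-range C1-sgEED cells and 99.7 in those of C1-sgKMT2D, against 118 in control cells.

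The 1934 cells of hashtag 2 had 11297540 UMIs and a median M share of 0.545. They held 3824 CPM of VIM, 19.6 of CDH1, 2407 of KRT14, 75.1 of COL1A1 and 134 of SPARC. Over all of these cells, those below the bound included, MGP was at 1.95 CPM, DCN at 0.620 and COL3A1 at 10.3. All cells of C1-sgEED held 261, 16.8 and 72.8 CPM of these genes, and all cells of C1-sgKMT2D 14.3, 52.7 and 59.0. EED was read at 8.94 and KMT2D at 2.83 CPM.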
